A study of Mus musculus with 6 samples.

How the data were processed

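RNA sequencing libraries were made from polyadenylated RNA of primary mouse hepatic stellate cells, 3 treated with 10 µM obeticholic acid (OCA) and 3 with the vehicle DMSO for 6 hours, 2 days after isolation. RNA was extracted with Trizol and silica columns, and libraries were prepared with the NEBNext Ultra RNA kit, per the labels' protocols. STAR, HOMER and the mouse build mm10 are named, per the submitters' processing notes. Their versions and settings, the handling of duplicate and multiply mapped reads, and the strand setting are not given in the sources used here.

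The authors deposited 1 table with 1 row for each of 24940 gene symbols. Each row names a RefSeq transcript with its mm10 coordinates and exonic length, and the table is described as unadjusted exon counts, per the file headers and name. The deposited values are counts in steps of 0.5 and were handled like expected counts, which need not be whole. The origin of the steps is not given in the sources used here. Between 26.5% and 29.8% of the values in a column were not whole, and no value departed from a multiple of 0.5. They were therefore rounded to whole numbers (ties to the even number) before any count test. No symbol was repeated, so each row stood for its gene, and 0 count columns were left out. Column totals ranged from 12260882 to 16336240 counts, and 3 counts correspond to between 0.181 and 0.251 CPM per library. Groups were taken from the sample labels, and each column was matched to its sample by its title. The libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom between 4.4 and 8.01 for the 6 pairs within groups.

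The comparison of OCA with DMSO used edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, dispersions with default settings, and the quasi-likelihood test (glmQLFit without robust estimation, glmQLFTest), two-sided, with no block for the replicate letter. It tested 12687 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the test's F value. The common biological coefficient of variation was 7.98%. CPM values are on TMM-scaled library sizes. The ratio of summed counts of a gene with few counts has an exact 95% interval, scaled for depth. The sums were rounded to whole numbers (ties to the even number) for the ratio and its interval. The design, alternatives, naming rule and 33 gene lists were fixed before the data were examined. Lists came from general knowledge of stellate cells, bile acid signalling and liver cell types, and the 29 lists with at least 5 tested members were tested with camera from limma 3.58.1 (preset inter-gene correlation of 0.01), adjusted over the lists. camera was repeated with an estimated correlation, and fry was the second test. camera called 12 lists, 8 higher and 4 lower. With an estimated correlation it called 0 of the 29. fry called 6: FXR target genes, hormone and vasoactive receptors, BMP response genes, retinoid genes, bile acid and sterol transporters and enzymes, and endothelial markers.

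Genes were named by a fixed rule. It takes Nr1h4, Gpbar1 and Nr0b2 in any case. It takes the 15 genes with the largest positive and the 15 with the largest negative log2 fold change among those with adjusted p under 0.05, a mean of at least 5 CPM over the 6 libraries and the same direction in all 9 pairs of an OCA and a DMSO library. From each list it takes up to 4 members with the smallest p among those past the threshold or, where none passes, up to 2 with the highest mean CPM for their values only. It also takes the 5 genes with the smallest p. Not every gene that the rule allows is named. Members of a list given only as its complete count of calls, and genes said to be named after their values were seen, fall outside it.

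Alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings, 3 other filters, a replicate block, robust estimation, a test against a fold change of 1.5 and leaving out each library. Others were added after the data had been seen: unrounded counts, the fit without OCA B and DMSO A, camera on log2 CPM, camera without a list's largest member, and offsets from a loess curve fitted in each library on transcript length, counts per base, both, or GC content. GC content came from GENCODE M21 transcripts of the same build, matched for 23413 rows by RefSeq identifier and 1235 by symbol, with 292 unmatched.

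The fit was tested on simulated data for the comparison of OCA with DMSO, with 12687 genes of which 200 were changed. Genes were drawn independently from the observed means, library sizes and the trend of the dispersions. Shifts shared by many genes within a group, and counts that grow less than depth, were not simulated. Errors from these sources are therefore not covered. The fit recovered 54% of 50 genes changed by 1.3-fold, 90% of 50 at 1.5-fold, 88% of 50 at 2-fold and 100% of 50 at 3-fold. It called 7 unchanged genes. With a length trend added to the simulated libraries, 366 unchanged genes were called without the length offsets and 4 with them. The added trend fell with length in OCA A and OCA C and rose in DMSO A and DMSO C. Its size was preset, equal in these libraries and not fitted to the observed trends, so 366 is no estimate for the real libraries. No effect of OCA on long transcripts was simulated, so the test does not show whether the offsets spare one.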

Results

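Gene expression was measured by RNA sequencing in 6 libraries of primary mouse hepatic stellate cells, the vitamin A-storing pericytes of the liver that turn into matrix-producing myofibroblasts when activated. The cells came from female C57BL/6JBomTac mice and were treated 2 days after isolation. For 3 libraries the cells received 10 µM obeticholic acid (OCA), a semisynthetic bile acid that activates the nuclear receptor FXR, and for 3 the vehicle dimethyl sulfoxide (DMSO), both for 6 hours. The deposited table gives exon counts for 24940 genes. Column totals were 13186608.5 counts in OCA A, 13234570 in OCA B, 12829226 in OCA C, 16336240 in DMSO A, 12260882 in DMSO B and 15104035.5 in DMSO C. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values below measure only the spread between these libraries, which may be technical. Values are CPM, counts scaled to a common library total, as mean ± SD over n = 3 libraries. Fold changes are OCA over DMSO with their standard error (SE), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counting intervals and floors cover counting error only.

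The comparison asks which transcripts of stellate cells respond to an FXR agonist, so the receptor and its known targets come first. FXR itself, encoded by Nr1h4 (NM_001163504, mm10 chromosome 10, 89454234 to 89533622, minus strand), was well expressed and was lower under OCA. It had 84.0 ± 2.43 CPM in DMSO and 65.8 ± 2.60 CPM in OCA, a log2 fold change of -0.35 (SE 0.07, adjusted p = 0.00535). All 3 OCA libraries lay below all 3 DMSO libraries. The membrane bile acid receptor gene Gpbar1 was near the detection limit, with 4 counts over the DMSO libraries, all in DMSO B. It had 5 counts over the OCA libraries, all in OCA B. Rxra, the dimerisation partner of FXR, had 367 ± 15.6 CPM in DMSO and 433 ± 8.88 CPM in OCA (log2 fold change 0.24, SE 0.07, adjusted p = 0.0487). That call was lost when OCA A, OCA B, OCA C, DMSO A or DMSO C was left out.

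Among 12 tested FXR target genes, 2 rose and the other 10 did not pass the test. Abcb11, the bile salt export pump (NM_021022, chromosome 2, 69238282 to 69342616, minus strand), went from 0.159 ± 0.0263 to 4.89 ± 0.592 CPM. Its counts were 6.5 over the DMSO libraries and 190.5 over the OCA libraries. With both sums rounded to whole numbers (ties to the even number), the depth-scaled ratio was 35.5, with a 95% counting interval of 16 to 98.1. The ratio of the unrounded sums is smaller, since rounding lowers the small DMSO sum. The fitted log2 fold change was 4.86 (SE 0.47, adjusted p = 1.36e-06), the largest positive value among the genes called. Osgin1, an oxidative stress-induced growth inhibitor (NM_027950, chromosome 8, 119437162 to 119446256, plus strand), went from 79.9 ± 5.74 to 221 ± 14.9 CPM (log2 fold change 1.47, SE 0.07, adjusted p = 6.5e-11). Nr0b2, which encodes the FXR-induced repressor SHP, had 0 counts in DMSO, where a floor of 3 counts over the group corresponds to 0.0683 CPM, and 3.5 counts in OCA. Slc51b had 0 counts in all libraries, Slc51a had 4.5 counts in DMSO and 0 in OCA, Fgf15 had 2.5 and 8, and Fabp6 had 0 and 1. These 5 genes had at most 8 counts over a group, so small changes cannot be measured at this depth, and none rose to the counts of Abcb11.

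The FXR target list as a whole had a median log2 fold change of 0.04 and a mean of 0.52, with 6 members above 0 and 6 below. camera, a competitive test of a list against all other genes, called it higher (adjusted p = 0.00011), and the call was lost with an estimated correlation (adjusted p = 0.191), on log2 CPM (adjusted p = 0.115) and with the length and density trend (adjusted p = 0.26). Adjusted over the list alone, 4 members passed upward and 2 downward. The list of bile acid and sterol transporters and enzymes had 2 of 13 tested members higher, Abcb11 and the organic anion transporter Slco3a1 (241 ± 13.6 to 331 ± 5.62 CPM, log2 fold change 0.46, SE 0.07, adjusted p = 0.00023), and 1 lower, Nr1h4. Adjusted over the list alone, 3 passed upward and 1 downward. Its camera call (higher, adjusted p = 0.0122) was lost without Abcb11 (adjusted p = 0.361), without OCA B (adjusted p = 0.0837), without DMSO B (adjusted p = 0.055), on log2 CPM (adjusted p = 0.115) and with an estimated correlation (adjusted p = 0.2).

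**Figure D1:**
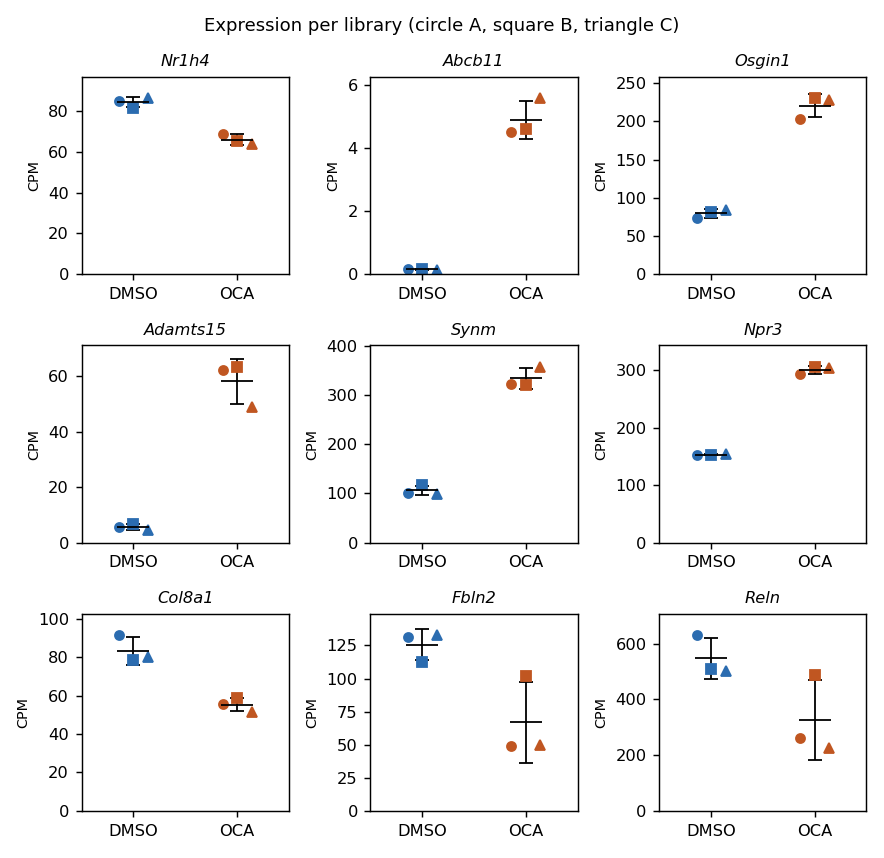
Expression of 9 named genes in each library. The y axis gives CPM from 0, the x axis the group; points are libraries (circle A, square B, triangle C) and the bar with whiskers is the mean ± SD over n = 3. Nr1h4 lies between 63.7 and 68.8 CPM in OCA and between 81.3 and 86 CPM in DMSO, while for Fbln2 and Reln OCA B stands nearer the DMSO libraries than OCA A and OCA C do.

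Across the transcriptome, 276 genes were higher and 384 lower under OCA among 12687 tested, and 2405 had an unadjusted p under 0.05. The higher genes changed more: 49 rose by more than 2-fold, and 7 fell by more than 2-fold. The median size of the log2 change was 0.51 among higher genes and 0.39 among lower ones. The groups did not overlap in 271 of the higher and 357 of the lower genes. Of all tested genes, 22.9% had non-overlapping groups, where chance gives 10%. Both counts depended on single libraries. The number of higher genes was 161 without OCA A and 164 without DMSO C. The number of lower genes was 104 without OCA A, 758 without OCA B, 126 without OCA C, 104 without DMSO A, 202 without DMSO B and 230 without DMSO C. All 6 fits that left out 1 library called 138 of the 276 higher genes (50%) and 67 of the 384 lower genes (17.4%).

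**Figure D2:**
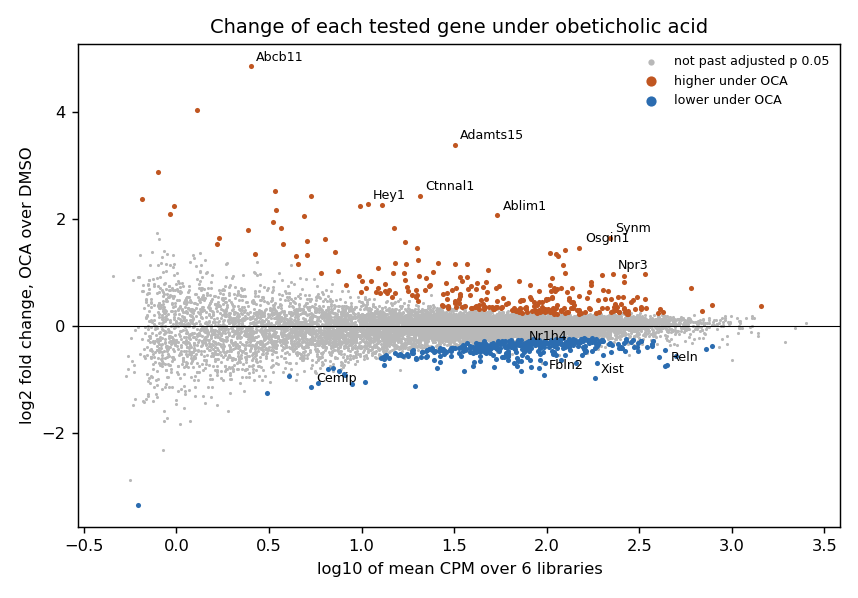
Change of each of the 12687 tested genes against its level. The x axis is the log10 of the mean CPM over the 6 libraries and the y axis the log2 fold change of OCA over DMSO; coloured points passed adjusted p of 0.05, 276 higher and 384 lower. Abcb11 and Adamts15 have log2 fold changes of 4.86 and 3.39.

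Among genes with a mean level of 5 CPM or more, Adamts15 had the largest increase. Adamts15, a secreted metalloprotease that cleaves versican (NM_001024139, chromosome 9, 30899155 to 30922452, minus strand), rose from 5.61 ± 1.06 to 58.2 ± 8.16 CPM (log2 fold change 3.39, SE 0.14), and it had the smallest p of all genes (adjusted p = 1.25e-11). Ctnnal1, an alpha-catenin-like protein, rose from 6.37 ± 1.04 to 34.9 ± 2.16 CPM (adjusted p = 4.77e-10). The actin-binding Ablim1 rose from 20.7 ± 1.22 to 87.4 ± 12.5 CPM and the intermediate filament protein Synm from 106 ± 9.93 to 334 ± 21.1 CPM. St3gal5, the ganglioside GM3 synthase, rose from 68.8 ± 5.25 to 184 ± 6.85 CPM (log2 fold change 1.42, SE 0.07). The transcription factor genes Hey1 (3.69 ± 1.02 to 17.9 ± 3.53 CPM), Tcf23 (3.37 ± 1.16 to 16.2 ± 3.40 CPM) and Sox9 (2.52 ± 0.857 to 7.69 ± 2.45 CPM) rose from low levels. So did the Wnt pathway genes Lypd6 (log2 fold change 2.27, SE 0.17) and Fzd9 (log2 fold change 1.63, SE 0.24). Shisa6, Clstn3, Eepd1 and Crybg1 had log2 fold changes of 2.43, 1.84, 1.57 and 1.46. Each of these genes was called in every fit that left out 1 library.

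Decreases at a mean level of 5 CPM or more were smaller. Below that level Prrt3, named after its values were seen, had the lowest log2 fold change of all genes called (-3.34, SE 0.80, 1.14 ± 0.411 to 0.103 ± 0.117 CPM, adjusted p = 0.0192). The hyaluronan-degrading Cemip had a log2 fold change of -1.14 (SE 0.28, adjusted p = 0.0223), and the call was lost without OCA A, OCA C, DMSO A or DMSO C. Rgs4, a regulator of G protein signalling, fell from 12.2 ± 1.20 to 5.70 ± 2.38 CPM (adjusted p = 0.00919), a call lost without DMSO A. Xist, the noncoding RNA of the inactive X chromosome, fell from 242 ± 51.2 to 123 ± 47.2 CPM (log2 fold change -0.97, SE 0.17, adjusted p = 0.00175). Tsix, on the opposite strand of Xist, had a log2 fold change of -1.12 (SE 0.18). The strand setting of the counting is not given in the sources used here, so the counts of this antisense pair may be shared and their values are uncertain. Agrn, which encodes the basement membrane proteoglycan agrin, fell from 45.8 ± 2.54 to 25.5 ± 10.8 CPM, and the microtubule-associated Nav2 from 93.3 ± 16.5 to 52.2 ± 14.1 CPM. The lysosomal mannosidase Man2b1 fell from 32.5 ± 2.95 to 19.0 ± 3.07 CPM (log2 fold change -0.78, SE 0.12, adjusted p = 0.000646). Xist, Tsix, Agrn, Nav2 and Man2b1 were called whichever library was left out. The calls of Xist, Agrn and Nav2 were lost with robust estimation, and those of Xist and Agrn also with DESeq2.

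Lower genes had long transcripts. Their median transcript length was 5987.5 bases, against 3355.5 bases for higher genes and 2866 bases for tested genes that were not called. The longest eighth of tested genes, from 5780 bases up, held 201 of the 384 lower genes and 36 of the 276 higher genes, and its median log2 fold change was -0.14, against 0.10 in the shortest eighth. The libraries also differed along this axis within groups: OCA B had the highest value of its group in 77.1% of the lower genes and DMSO A in 67.7%, against 33.2% and 35.9% of all tested genes. In alternatives chosen after the data had been seen, leaving out OCA B and DMSO A gave 339 higher and 605 lower genes. Offsets for a length trend in each library gave 347 higher and 228 lower genes, which moves the share of higher genes from 41.8% to 60.3%.

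**Figure D3:**
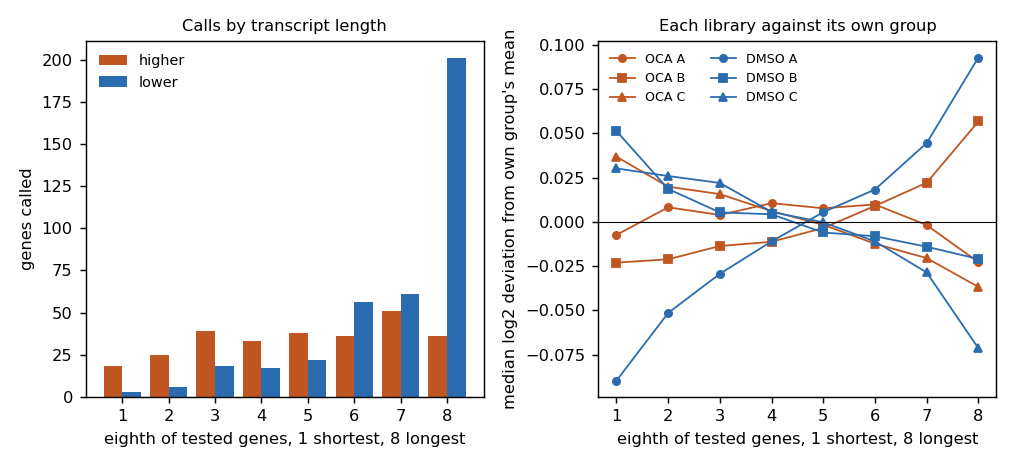
Calls and libraries by transcript length. Left, the number of genes called higher or lower (y axis) in each eighth of the tested genes from shortest to longest (x axis); right, the median log2 deviation of each library from its own group's mean in the same eighths. The longest eighth holds 201 lower and 36 higher calls, and DMSO A and OCA B lie above their groups there, by 0.09 and 0.06.

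Receptors for hormones and vasoactive signals formed the list with the smallest camera p, though 7 of the other lists called had a larger median change. Of 19 tested members 6 rose, none fell and 13 did not pass, the same 6 passing upward and 1 downward when adjusted over the list alone. Npr3, the natriuretic peptide clearance receptor, rose from 153 ± 1.11 to 301 ± 7.04 CPM (log2 fold change 0.98, SE 0.06, adjusted p = 2.76e-09). The angiotensin II receptor gene Agtr1a rose from 125 ± 8.91 to 222 ± 13.6 CPM, the sphingosine 1-phosphate receptor gene S1pr3 from 168 ± 6.66 to 263 ± 3.14 CPM, and the vasoactive intestinal peptide receptor gene Vipr1 from 77.7 ± 4.99 to 132 ± 12.2 CPM. The other members called were Adra1b (log2 fold change 0.46) and Pth1r (log2 fold change 0.34). Npr3, Agtr1a, S1pr3 and Vipr1 were called in every fit that left out 1 library. The list was higher by camera (adjusted p = 1.5e-08, median log2 fold change 0.13), with adjusted p = 0.0726 with an estimated correlation.

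Among 13 tested BMP response genes, 4 rose and none fell: Hey1, the ligands Bmp2 (60.5 ± 5.92 to 102 ± 9.75 CPM, log2 fold change 0.76, SE 0.08) and Bmp4, and the inhibitory Smad6 (109 ± 4.32 to 154 ± 5.90 CPM, log2 fold change 0.49, SE 0.06). Bmp4, with 17.0 ± 1.53 and 23.5 ± 3.14 CPM (adjusted p = 0.0448), lost its call without OCA A, OCA C, DMSO A, DMSO B or DMSO C, and with DESeq2, limma-voom and 2 other scalings. Adjusted over the list alone, 4 passed upward and 1 downward. The Id genes, direct targets of BMP signalling, were not called; Id1 had a log2 fold change of -0.14 (SE 0.13) and Id3 of 0.13 (SE 0.07), both named after their values were seen. camera called the list higher (adjusted p = 0.00178), and the call was lost without Hey1 (adjusted p = 0.0815), with an estimated correlation (adjusted p = 0.191), on log2 CPM (adjusted p = 0.177) and with the length and density trend (adjusted p = 0.511).

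Retinoid metabolism and retinoic acid receptor target genes had 3 of 19 tested members higher and 1 lower, with 7 upward and 2 downward when adjusted over the list alone. Rara, a retinoic acid receptor gene, rose from 48.0 ± 3.62 to 68.9 ± 6.81 CPM and the retinol dehydrogenase gene Rdh10 by a log2 fold change of 0.51 (SE 0.09), while Dhrs3, which turns retinal back into retinol, fell from 41.2 ± 4.06 to 28.0 ± 2.35 CPM (log2 fold change -0.56, SE 0.10, adjusted p = 0.00262). The third higher member was Rxra. The list was higher by camera (adjusted p = 0.0111, median log2 fold change 0.19), with adjusted p = 0.2 with an estimated correlation and 0.107 with the length and density trend. Interferon response genes had 24 of 25 tested members above 0 and a median log2 fold change of 0.25. 6 of them rose and none fell over all genes, and 10 rose when adjusted over the list alone. Ifit3 rose from 31.7 ± 0.869 to 50.9 ± 7.38 CPM (adjusted p = 0.000295). Its close paralog Ifit3b, with which it may share reads, had a log2 fold change of 0.84 and lost its call without OCA A. Oas1a, a double-stranded RNA sensor gene, had 24.1 ± 2.32 and 34.2 ± 4.84 CPM, a call lost without OCA A, DMSO A or DMSO B. The interferon list was higher by camera (adjusted p = 8.95e-07), with adjusted p = 0.447 with an estimated correlation and 0.169 by fry.

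Collagen and other extracellular matrix genes mostly had changes in the other direction, though most did not pass the test. Of 33 tested members 7 fell, none rose and 26 did not pass, and 29 of the 33 had a log2 fold change below 0. Adjusted over the list alone, 14 passed downward and 1 upward. Col8a1 fell from 83.3 ± 7.31 to 55.3 ± 3.49 CPM (log2 fold change -0.59, SE 0.08, adjusted p = 0.000112) and Fbln2, encoding fibulin 2, from 126 ± 11.6 to 67.0 ± 30.6 CPM (adjusted p = 0.00416). The fibrillar collagen gene Col5a2 fell from 593 ± 4.37 to 402 ± 101 CPM, a call lost without OCA A. Fbln5 fell from 68.8 ± 4.83 to 46.4 ± 12.7 CPM, a call lost without OCA A, OCA C, DMSO A or DMSO B. Fbln2, Col5a2 and Fbln5 also lost their calls with robust estimation, and Fbln2 and Col5a2 with DESeq2. With the density trend Fbln5 had adjusted p = 0.0611, and with the length and density trend 0.0648. In OCA B, Fbln2 was at 102 CPM, against 49.0 in OCA A and 49.7 in OCA C. camera called the list lower (adjusted p = 5.8e-08, median log2 fold change -0.24), with adjusted p = 0.512 with an estimated correlation and 0.255 by fry. Matrix proteases had 6 of 21 tested members lower and 1 higher, or 9 and 2 when adjusted over the list alone. Plau, the urokinase gene, fell from 54.0 ± 0.569 to 38.5 ± 2.83 CPM, Adam19 from 285 ± 2.64 to 217 ± 19.0 CPM and Adamts1 from 338 ± 20.4 to 258 ± 17.7 CPM, while Mmp11 rose from 27.2 ± 2.85 to 40.5 ± 4.05 CPM. The protease list was lower by camera (adjusted p = 0.00104, median log2 fold change -0.32), with adjusted p = 0.255 with an estimated correlation and 0.0692 by fry.

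**Figure D4:**
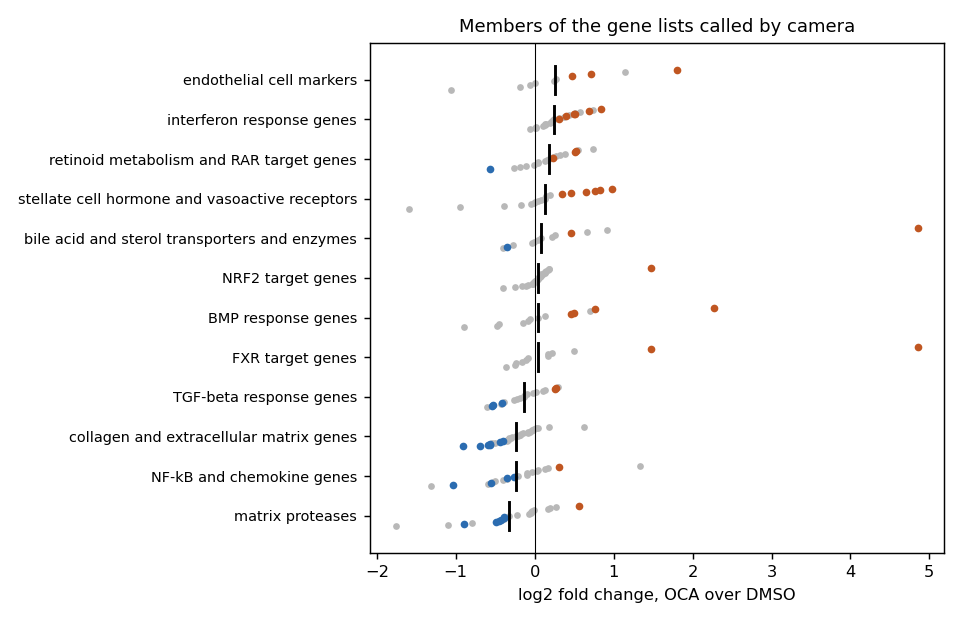
Members of the 12 gene lists that camera called. Each point is a tested gene, its x position the log2 fold change of OCA over DMSO, orange or blue where it passed adjusted p of 0.05 over all genes and grey where it did not; the black bar is the list's median. Medians run from -0.32 for matrix proteases to 0.26 for endothelial cell markers.

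TGF-beta response genes had 3 of 20 tested members lower and 2 higher, with 8 and 3 when adjusted over the list alone. The lower members were Skil (128 ± 7.83 to 89.2 ± 13.8 CPM, log2 fold change -0.52), the epithelial-mesenchymal transition regulator Snai1 (60.5 ± 2.82 to 41.6 ± 6.02 CPM) and the pseudoreceptor gene Bambi (64.1 ± 1.74 to 48.3 ± 1.71 CPM). Skil and Bambi encode inhibitors of TGF-beta signalling. Ski, another inhibitor, was higher (log2 fold change 0.26, adjusted p = 0.0344), a call lost without OCA A, OCA B, OCA C, DMSO A or DMSO C, and the other higher member was Tgfbi. The list was lower by camera (adjusted p = 0.0111, median log2 fold change -0.14), a call lost without OCA A (adjusted p = 0.0732), without DMSO B (adjusted p = 0.0699), on log2 CPM (adjusted p = 0.0755), with an estimated correlation (adjusted p = 0.528) and by fry (adjusted p = 0.196). NF-kB and chemokine genes had 4 of 20 tested members lower, Nfkbiz, Ptgs2, Icam1 and Vcam1, and 1 higher, Nfkbia, which encodes an inhibitor of NF-kB. Adjusted over the list alone, 6 were lower and 2 higher. Ptgs2, the cyclooxygenase-2 gene, fell from 51.9 ± 3.25 to 35.4 ± 6.16 CPM (log2 fold change -0.55, SE 0.11, adjusted p = 0.0043) and Nfkbiz by a log2 fold change of -1.04, a call lost without DMSO C. Nfkbia had 77.1 ± 5.85 and 95.2 ± 2.59 CPM, a call lost without OCA A, OCA C, DMSO A or DMSO B, and Icam1 lost its call without OCA A. The list was lower by camera (adjusted p = 0.00996, median log2 fold change -0.24), with adjusted p = 0.37 with an estimated correlation, 0.0883 by fry and 0.0565 on log2 CPM.

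Markers of stellate cell quiescence were not called as a group. Of 27 tested members 3 rose and 2 fell, with 9 and 4 when adjusted over the list alone (camera adjusted p = 0.199, median log2 fold change 0.12; adjusted p = 0.0376 without DMSO B). The transcription factor gene Tcf21 rose from 62.0 ± 5.42 to 86.4 ± 4.43 CPM (log2 fold change 0.48, SE 0.08, adjusted p = 0.000756). Sod3, with 98.4 ± 10.9 and 130 ± 26.4 CPM, was also higher, a call lost without OCA B, DMSO A or DMSO C. Reln fell from 547 ± 73.6 to 325 ± 143 CPM, a call lost without OCA A, OCA C or DMSO A, and Rgs5 from 61.6 ± 6.27 to 45.8 ± 8.96 CPM, a call lost without OCA A, OCA C, DMSO A or DMSO B. Sod3, Reln and Rgs5 also lost their calls with robust estimation, and Reln with DESeq2. Reln lost its call with the density trend too (adjusted p = 0.0653) and with the length and density trend (adjusted p = 0.0702), as did Sod3 and Rgs5. Of 19 tested myofibroblast contractile genes, 1 was called, both over all genes and adjusted over the list alone. This was Lmod1, with 63.4 ± 2.36 and 51.4 ± 4.85 CPM (log2 fold change -0.30, SE 0.08, adjusted p = 0.0402), a call lost without OCA B, OCA C, DMSO A, DMSO B or DMSO C. The contractile list was not called by camera (adjusted p = 0.196, median log2 fold change 0.09), although it was called higher without DMSO B (adjusted p = 0.000658). With the length and density trend its direction turned to lower, without a call (adjusted p = 0.117). These genes had a median of 2.98 counts per base. Depth was taken from the median count of genes with 0.03 to 0.1 counts per base, whose slope is therefore 1 by definition. Within groups, counts of genes with over 3 counts per base grew with this depth at a slope of 0.252. Genes with under 0.03 counts per base had a slope of 1.01. All tested genes with 1 to 2 counts per base had a median log2 fold change of 0.08 and those with over 3 had 0.13, so the median of the contractile list lies in the range of densely covered genes.

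NRF2 target genes had 1 of 29 tested members called, Osgin1, over all genes and adjusted over the list alone. The list's camera call (higher, adjusted p = 0.012, median log2 fold change 0.05) was lost without Osgin1 (adjusted p = 0.425), without OCA C (adjusted p = 0.0652), without DMSO A (adjusted p = 0.131), on log2 CPM (adjusted p = 0.145), with an estimated correlation (adjusted p = 0.696) and by fry (adjusted p = 0.255). With the length and density trend the direction turned and the list was called lower (adjusted p = 0.0335). Single genes were called in some of the lists that camera did not call. Of 14 glucocorticoid response genes, the kinase gene Sgk1 rose from 120 ± 3.91 to 178 ± 8.44 CPM (adjusted p = 1.02e-05) and Errfi1, an inhibitor of the EGF receptor, from 157 ± 7.54 to 221 ± 17.1 CPM (adjusted p = 0.000153), while Pdk4 was lower; adjusted over the list alone, 2 passed upward and 2 downward. That list's median log2 fold change was -0.05 and its test pointed upward (camera adjusted p = 0.595). Of 22 PPAR target and lipid droplet genes 2 fell, Angptl4 (log2 fold change -0.55, adjusted p = 0.000563) and Pdk4 (24.8 ± 1.35 to 17.7 ± 1.27 CPM), the latter call lost without OCA A, OCA C, DMSO B or DMSO C. Adjusted over the list alone, 3 passed upward and 4 downward. The median of the PPAR list was 0.03, its mean -0.01 and its test downward (camera adjusted p = 0.812). Of 27 immediate early genes 3 fell and 2 rose, with 4 and 6 when adjusted over the list alone (camera adjusted p = 0.646), and Myc fell from 111 ± 2.45 to 79.8 ± 12.3 CPM (adjusted p = 0.00251). Of 28 integrated stress response genes 1 rose, also when adjusted over the list alone, Mthfd2 (log2 fold change 0.34, adjusted p = 0.0029). That list had camera adjusted p = 0.0713, and was called higher without OCA A (adjusted p = 0.00571), without DMSO C (adjusted p = 0.0337) and with no filter (adjusted p = 0.0323).

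No member was called in the lists for cholesterol synthesis (25 tested, camera adjusted p = 0.396), endoplasmic reticulum chaperones (22 tested, 0.887), heat shock (16 tested, 0.332), xenobiotic receptor targets (10 tested, 0.241), hypoxia and glycolysis (25 tested, 0.31) and the cell cycle (33 tested, 0.619). Counts adjusted over the list alone were also 0 for these 6 lists. Members with the highest levels were as densely covered as contractile genes: Hspa5 with 2.97, Hsp90ab1 with 5.05 and Pkm with 3.99 counts per base. Of 229 tested genes with 2 to 3 counts per base 0 were called, and of 93 with over 3, 1 was called. For such genes the missing call leaves open whether their RNA changed. cAMP and CREB response genes had 1 of 16 lower (Pde4b; camera adjusted p = 0.573), LXR target and lipogenic genes 1 of 17 lower (Abca1; 0.619), YAP and TEAD target genes 1 higher and 1 lower of 19 (F3 and Dlc1; 0.789) and p53 target genes 1 higher and 1 lower of 21 (Btg2 and Tnfrsf10b; 0.52). Adjusted over the list alone, these 4 lists had 1 higher and 2 lower, 0 and 1, 2 and 2, and 1 and 1. Each of the 6 called genes named here lost its call in at least 2 of the fits that left out 1 library. Abca1 went from a log2 fold change of -0.32 to -0.13 with the length trend (adjusted p = 0.355). With the length and density trend it had -0.11 (adjusted p = 0.429). Pde4b, F3, Dlc1 and Tnfrsf10b each lost their call with at least 1 trend on length or counts per base.

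Markers of other liver cells differed in level and in direction. The albumin gene Alb had 2.08 ± 0.769 CPM in DMSO and 2.30 ± 0.620 CPM in OCA. Summed over all members of a list, hepatocyte markers had 193 ± 12.1 CPM in DMSO and 206 ± 2.14 CPM in OCA, endothelial markers 735 ± 69.0 and 806 ± 47.3, and Kupffer cell and macrophage markers 22.8 ± 6.85 and 22.5 ± 2.52. Cholangiocyte markers had 9.90 ± 0.411 and 13.9 ± 1.86 CPM, lymphocyte markers 0.310 ± 0.186 and 1.46 ± 0.492, and portal fibroblast and mesothelial markers 186 ± 6.51 and 131 ± 36.0. Single genes hold most of 4 of these sums: Ass1 had 170 and 182 CPM of the hepatocyte sum, and Eng, named after its values were seen, 583 and 585 CPM of the endothelial sum. Fbln2 had 126 and 67.0 CPM of the portal fibroblast sum and Lck 0.201 and 1.10 CPM of the lymphocyte sum, and Sox9 rose by more than the cholangiocyte sum (2.52 to 7.69 CPM), so these 3 sums do not show a change of the whole marker group. Whether these transcripts came from other cells or from stellate cells was not tested. The lists for hepatocytes, macrophages, cholangiocytes and lymphocytes had fewer than 5 tested members and were not tested as lists. In them, 0 of 4, 0 of 4, 1 of 3 and 1 of 1 tested members were called, all higher. The 2 called were Sox9, described above, and Lck, with 0.201 ± 0.0375 and 1.10 ± 0.295 CPM, a call lost whichever library was left out. Endothelial cell markers had 3 of 10 tested members higher and none lower, with 3 and 1 when adjusted over the list alone. Esam, a junction protein gene, rose from 83.7 ± 1.06 to 137 ± 7.83 CPM (log2 fold change 0.71, SE 0.07, adjusted p = 1.05e-06) and the orphan receptor gene Gpr182 from 1.07 ± 0.430 to 3.81 ± 0.182 CPM. Flt1, with 26.8 ± 4.20 and 37.2 ± 5.09 CPM, lost its call without OCA A, DMSO A or DMSO C. The endothelial list was higher by camera (adjusted p = 0.00414, median log2 fold change 0.26), a call lost without OCA B (adjusted p = 0.0837), on log2 CPM (adjusted p = 0.0755) and with an estimated correlation (adjusted p = 0.191). Of 9 tested portal fibroblast and mesothelial markers 1 fell, Fbln2, also when adjusted over the list alone. That list had a median log2 fold change of 0.01, a mean of -0.30 and a test pointing downward (camera adjusted p = 0.439; adjusted p = 0.0182 without OCA B).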

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

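The settings named as trends, log2 CPM, a list's largest member and the fit without both OCA B and DMSO A were chosen after the data had been seen. Of the 46 named genes called higher, 33 were called in every setting that tested them, leaving aside the test against 1.5-fold. Of the 40 called lower, 14 were. Abcb11 and Gpr182, among the 33, had too few counts in DMSO to be tested with the filter of 10 counts in every library. None of the 86 was called in the opposite direction in any setting. The number of higher genes (276) ranged from 161 to 363 and of lower genes (384) from 104 to 758 when 1 library was left out, and these fits have fewer samples. Against a fold change of 1.5, glmTreat called 38 genes higher and 0 lower. Without a filter 703 genes were lower. Lower genes numbered 228 with the length trend, 237 with the length and density trend and 605 without OCA B and DMSO A. Of these shifts, the cause was not tested beyond the trend tests given further on. Other scalings, DESeq2, limma-voom and the other filters stayed within 1.5 times of both counts. The letters gave no clear pairing of the libraries. Deviations of OCA and DMSO libraries with the same letter correlated at 0.00051 (A), -0.043 (B) and 0.054 (C). Of 3 OCA libraries, 1 correlated best with its own letter. These correlations cannot exclude a pairing, and the labels leave it open. With the letter as a replicate block, 306 genes were higher and 508 lower, and 12 lists were called.

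Of the lists, camera called 12. The number was 0 with an estimated correlation, 6 with fry, 5 on log2 CPM, and 11 to 13 when 1 library was left out. The estimated correlation was 0.502 for collagen and matrix genes and 0.392 for interferon genes. It was below the preset 0.01 for hormone and vasoactive receptors (-0.00809), BMP response (0.0021), retinoid (0.00197), bile acid (-0.0288) and endothelial genes (-0.0226). For the lists below the preset, a higher correlation of members cannot account for the lost call. Without adjustment, camera's p rose from 5.16e-10 to 0.0025 for receptors and from 0.000368 to 0.0204 for BMP response genes. The estimated setting thus changes the test by more than the correlation. A call lost with it, in any list, does not by itself show correlated members. What else changed was not tested. NRF2 target genes turned from higher to lower with the length and density trend (adjusted p = 0.0335), where log2 CPM without the trend gave no call, and p53 target genes were called lower with that trend (adjusted p = 0.0316). The mean level of Nr1h4 stayed between 82.9 and 85.3 CPM in DMSO and between 64.4 and 66.9 CPM in OCA when 1 library was left out. Depth limits genes near 1 CPM, where 3 counts are up to 0.251 CPM. Densely covered genes are limited too, since their counts grew less than depth.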

Other observations

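All tests in this part except the held-out test and the Notch list were chosen after the results had been seen, and the genes in this paragraph were chosen after their values were seen. Outside the naming rule, the genes with the smallest p were nearly all higher. Syt9, a synaptotagmin of vesicle fusion, rose from 62.8 ± 2.77 to 161 ± 13.5 CPM (log2 fold change 1.35, SE 0.07), and Acap1, an ARF6 GTPase-activating protein gene, from 58.0 ± 5.26 to 150 ± 7.10 CPM. Slc8b1, the mitochondrial sodium/calcium exchanger, rose from 76.3 ± 1.78 to 169 ± 13.5 CPM. Marcksl1, Epb41l1, Enah and Pkp2 had log2 fold changes of 0.96, 0.93, 1.05 and 0.71. Il4ra, the interleukin 4 receptor gene, rose from 188 ± 4.50 to 336 ± 17.8 CPM, and Adcy5, an adenylyl cyclase gene, from 74.5 ± 8.24 to 138 ± 10.8 CPM. Wisp1, a matricellular protein gene, fell from 114 ± 5.35 to 66.8 ± 9.30 CPM (log2 fold change -0.77, SE 0.08), and the Wnt antagonist gene Dact1 from 88.7 ± 3.93 to 56.3 ± 5.01 CPM.

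Hey1 can respond to Notch as well as to BMP signals, so a list of 10 Notch genes without Hey1 was written before their values were seen. The allowance for spread in its bound was added after the values were seen. Of the 6 tested, none was called, and their median log2 fold change was -0.0299 (bootstrap SE over these genes 0.135). Hes1 had 41.2 ± 2.33 CPM in DMSO and 40.5 ± 3.03 CPM in OCA, and Hey2 had a log2 fold change of 0.73 (SE 0.29, adjusted p = 0.174). With members moving both ways, the hypothesis that Notch activity raised Hey1 cannot be told apart from its absence.

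Genes lower under OCA sat in long transcripts: 52.3% of them, and 13% of the higher genes, lay in the longest eighth. A trend with counts per base between libraries as the whole cause is argued against, for these 6 libraries only. After a refit of all genes with density offsets, 38.8% of lower calls and 15.8% of higher calls lay there (binomial SE of the difference 3.65). The binomial and bootstrap SEs in this paragraph take genes as independent. All genes come from the same libraries, so these SEs do not measure the spread between libraries. With length offsets the shares were 20.2% and 23.6% (SE 3.50), against 12.5% of tested genes, and 228 genes were lower in place of 384. The difference between lower and higher genes closed, in part because the share of higher genes rose, while both stayed above that of tested genes. Of the 384, 189 were still called, with a median log2 fold change of -0.293 (bootstrap SE 0.0102) in place of -0.389 (SE 0.00954). A length trend between libraries cannot be told apart from a lowering of long transcripts by OCA, because the offsets remove both. The length trend was taken as the median log2 deviation in the longest minus the shortest eighth. It was -0.121 in OCA A, -0.0308 in OCA B and -0.186 in OCA C. In DMSO A it was 0.286, in DMSO B 0.0324 and in DMSO C 0.012. The groups do not overlap, so the trend follows them, but OCA B lies close to DMSO B and DMSO C. Chance alone separates groups of 3 in 10% of cases. Spread between libraries that also exists within groups was not tested apart from the values that raised it. A lowering by OCA stays open too. Calls made on 4 libraries were compared with the held-out OCA and DMSO library over the 9 held-out pairs. They went the same way for 65% to 100% of lower genes and for 79.7% to 100% of higher genes. With OCA B held out, the shares of lower genes were 88.9%, 78.2% and 65%. With OCA A or OCA C held out they were 94.6% to 100%, on 33 to 53 calls. A held-out pair shares a trend that follows the groups, so this test cannot separate OCA from that trend.

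Abcb11 rose from near 0. More RNA from hepatocytes, where this pump is abundant, in the OCA cultures is argued against by Alb. It rose by 0.216 CPM (SE 0.571) while Abcb11 rose by 4.73 CPM (SE 0.342). Alb cannot tell whether Abcb11 rose within any hepatocytes present in both groups, which was not tested. Reads shared with a paralog are argued against by the other 14 tested Abcb and Abcc genes, where the largest log2 fold change was 0.217 (SE 0.0702, Abcb6). A response to OCA in stellate cells remains as a hypothesis, beside a response in such hepatocytes, found and tested on the same data.

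Contractile genes were not called as a group, and counts that grow less than depth may have hidden changes there. Depth was again taken from the genes with 0.03 to 0.1 counts per base. Within groups, the log2 counts of the 19 tested genes grew with it at a slope of 0.282 (SE 0.09), against 0.788 (SE 0.0588) for all tested genes. Whether their RNA changed stays open.

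The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 276 higher and 384 lower genes and 12 lists, and was the 1 split to reach each of these. The highest of the other splits gave 0 genes in either direction and 5 lists. Each of the other splits mixes OCA and DMSO libraries in both of its groups, so a treatment difference adds spread within them. Their 0 genes are therefore no null count for 276 and 384. These splits also hold more OCA libraries on 1 side, so their lists are not free of treatment.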
